A study of Mus musculus with 8 samples.

How the data were processed

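Polyadenylated RNA from mouse cells that the labels call adipocytes was sequenced in 8 samples, 4 labelled BMPR2 DELX and 4 labelled ROSA, the control of the study. The deposited files, 1 per sample, hold raw read counts per Ensembl gene. Per the submitters' processing notes, GRCm38, STAR 2.5.2b and HTSeq were used, with no role or order given, and the files have the layout of STAR's gene counts, with an unstranded, a same-strand and an opposite-strand column. The annotation release, the read layout and any filter before counting are not stated. The values are whole numbers with different totals per sample, so no normalization by the authors was found in the deposited counts.

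Each file has 49671 gene rows and 4 lines that name no gene (unmapped, multimapping, outside annotated genes and ambiguous reads). Those 4 lines were kept out of library sizes and tests, and together they held 14.7% to 22.0% of the reads of a sample. Of the strand-assigned counts, 93.4% were in the opposite-strand column, which was used under the rule that a stranded column is taken where it holds over 80% of them. Totals of this column ran from 28799445 to 43684785 counts per sample. A count of 0 allows up to 3 counts, which is 0.0687 to 0.104 counts per 1e6 counts (CPM) in these libraries, a limit for counting error only. GENCODE M21 supplied symbols, biotypes and GRCm38 positions, and 49412 of the gene IDs were found in it.

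Genes with enough counts were kept with filterByExpr, which left 14887. Trimmed mean of M values (TMM) factors were applied, and BMPR2 DELX was compared with ROSA by the edgeR 4.0.16 quasi-likelihood test with robust dispersion in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of its F statistic. Group levels are TMM-scaled CPM with the SD over 4 libraries, and levels of genes left out by the filter are CPM of the unscaled totals. A library's score for a gene list is the mean log2 CPM of the tested members, with a prior count of 2. The labels state no pairing of the samples, so the replicate number was not a term of the model. The labels also do not say whether the samples came from separate animals, so the p-values measure the spread between samples.

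A total of 45 gene lists (signalling, metabolism, stress responses and markers of other cell types) was fixed before the data were examined. The 37 with at least 5 tested members were compared with the other genes by camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation, and fry, were alternatives. Counts adjusted over the list alone stand beside counts over all genes tested.

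The rule for named genes was also fixed before the data were examined. It takes Bmpr2. It then takes, in each direction, the 8 genes with the largest fold and the 6 with the smallest p among called genes with a mean CPM of at least 1, no overlap between the groups and no predicted, clone or pseudogene name. It last takes up to 4 members of each described list by smallest p. Genes outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

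The model was tested on simulated data of the size of BMPR2 DELX against ROSA, with 4 libraries in each group and 14711 genes left after the filter. A planted log2 change of 0.5 was called in 19 of 67 genes, a change of 1 in 47 of 67 and a change of 2 in 62 of 66. Unchanged genes made up 5.88% of all calls. In a separate simulation, a list of 25 genes shifted by 0.5 was called and none of 40 unshifted lists was (0 of 40). Genes were simulated independently of each other, so this does not test lists whose members vary together. The cell cycle list, for example, had an estimated inter-gene correlation of 0.80.

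Other settings fixed before the data were examined were relative log expression and upper-quartile factors, DESeq2 1.42.0, limma voom with sample quality weights, no count filter, a filter at 1 CPM in 4 libraries, the unstranded count column, the replicate number as a block, and leaving out each library in turn. Settings chosen after seeing the data left out pairs of libraries or added a covariate. The covariate was an endothelial score, a macrophage score or the share of reads not assigned to a gene. All 35 splits of the 8 libraries into 4 and 4 were fitted with the same model. Annotated copies of Phgdh were found by blastn 2.17.0 against the GENCODE M21 transcripts. Figures were drawn with matplotlib 3.10.9. No sample was left out of the main comparison.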

Results

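RNA sequencing counts were obtained for 8 mouse samples labelled adipocytes, 4 from BMPR2 DELX mutant mice and 4 from ROSA control mice. Total counts assigned to genes ran from 28799445 to 43684785 per sample, with means over 4 libraries given as value ± SD throughout. The series has a single comparison, which asks how expression in BMPR2 DELX samples differs from that in ROSA samples. Differences are log2 fold changes of BMPR2 DELX over ROSA with their standard error, n = 4 per group, and adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

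Bmpr2 itself (ENSMUSG00000067336, GRCm38 chromosome 1, 59763400 to 59879014), the type II BMP receptor named in the mutant label, had similar total counts in both groups. Its level was 211 ± 17.6 CPM in BMPR2 DELX and 197 ± 17.05 CPM in ROSA. The log2 fold change was 0.10 ± 0.08 (SE), with an edgeR adjusted p of 0.47, and the libraries of the groups overlapped. A count per gene does not show which exons were present in the transcripts.

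The cells expressed a fibroblast and contractile gene set at high level. The labels call the samples adipocytes, but the counts do not show mature adipocytes as a main cell type. Adipoq, encoding adiponectin, had 0.0791 CPM in BMPR2 DELX and 0.0389 CPM in ROSA, and Lep, Plin1, Cidec, Cfd and Retn had at most 3 counts in any library, and the glucose transporter gene Slc2a4 had at most 0.297 CPM. Of 32 adipocyte identity genes in the annotation, 14 stayed under 1 CPM in all libraries. Genes that are not confined to mature adipocytes were expressed, and Pparg, the adipogenic nuclear receptor, had 22.5 and 15.6 CPM before scaling in BMPR2 DELX and ROSA, the fatty acid carrier Fabp4 had 51.9 and 59.0 CPM and Lpl, the lipoprotein lipase gene, had 217 and 136 CPM. The collagen gene Col1a1 and the smooth muscle actin gene Acta2 had 4974 and 6882 CPM in ROSA before scaling, and the TGF-beta responsive Thbs1 had 11738 ± 529 CPM in ROSA after it. The endothelial gene Pecam1 had 202 ± 123 and 203 ± 80.9 CPM and Emcn had 284 ± 176 and 305 ± 91.4 CPM before scaling in BMPR2 DELX and ROSA. The marker genes in this paragraph were chosen from the fixed lists after their values were seen.

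Of 14887 genes tested, 589 were higher and 766 were lower in BMPR2 DELX (9.10% of the genes), and 3920 had an unadjusted p below 0.05. Most changes were modest, since 697 of the 1355 called genes differed by less than 1.5-fold and 120 higher and 195 lower genes differed by more than 1 on the log2 scale. All libraries of one group lay above all of the other for 18.0% of the genes, against 2.86% by chance. The main component of the expression values, with 37.4% of the variance, separated the groups. With upper-quartile factors the split was 734 higher and 606 lower, or 54.8% higher, against 43.5% with TMM factors. Among fits that left out 1 library the count was lowest without ROSA 2, at 213 higher and 264 lower, and 207 and 263 of these were among the calls with all libraries.

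Within the naming rule, which leaves out pseudogenes, predicted and clone names, genes under a mean of 1 CPM and genes with overlapping groups, the largest rises were those of Crisp1, a secreted protein of the epididymis, Clca3b, and Lad1, a basement membrane anchoring protein, with log2 fold changes of 5.99 ± 1.48, 5.06 ± 1.20 and 3.29 ± 0.78. In ROSA they had 0.0527 ± 0.0899, 0.161 ± 0.137 and 0.224 ± 0.119 CPM, so the size of these folds rests on few control counts. All 3 were uneven and highest in BMPR2 DELX 3, where Crisp1 had 10.9 CPM against 0.469 to 1.47 in the other BMPR2 DELX libraries, Clca3b 15.4 against 0.670 to 5.86 and Lad1 5.25 against 0.492 to 2.40. Without 1 library their log2 fold changes ran from 4.22 to 8.08, 3.92 to 5.92 and 2.48 to 3.64, lowest without BMPR2 DELX 3 for each, and highest without ROSA 1 for Crisp1 and ROSA 2 for Clca3b. The epithelial genes Krt8, Krt7, Pax8 and Cdh16, chosen after their values were seen, followed the same order of BMPR2 DELX libraries, with 2.99, 5.97, 11.2 and 0.961 CPM of Krt8 before scaling in BMPR2 DELX 1 to 4. More even rises were found for Arntl2, a paralog of the clock factor Bmal1 (3.04 ± 0.38, edgeR adjusted p 0.0033), Cyp7b1, an oxysterol hydroxylase (2.95 ± 0.32, adjusted p 0.0019), and Ednra, the endothelin A receptor (2.20 ± 0.32, adjusted p 0.0050). Ggt5, a gamma-glutamyltransferase, rose by 2.44 ± 0.48 (3.30 without ROSA 4), and Pgr, the progesterone receptor, rose from 5.68 ± 3.12 to 25.1 ± 5.06 CPM. Within the same rule, the higher genes with the smallest p were the immune checkpoint ligand Cd276 (0.90 ± 0.06, adjusted p 1.3e-04), the aggrecanase Adamts4 (0.97 ± 0.09), the fibrillar collagen Col3a1 (1.25 ± 0.12), Igsf3 (0.62 ± 0.06), the heparan sulfate proteoglycan Sdc1 (1.12 ± 0.11) and the GTPase activator Arhgap6 (0.96 ± 0.10).

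Among lower genes within that rule, Elmod1 fell by 3.22 on the log2 scale, from 6.17 ± 2.54 to 0.663 ± 0.276 CPM. The activity-regulated gene Arc fell by 3.07 (2.28 without ROSA 2), with 29.6 and 62.1 CPM in ROSA 1 and ROSA 2 and 11.6 and 6.51 CPM in ROSA 3 and ROSA 4. The uroplakin Upk1b fell by 2.64, the vomeronasal receptor Vmn2r79 by 2.62 (1.93 without ROSA 1 and 3.21 without BMPR2 DELX 3), the histone H3 gene Hist1h3b by 2.35, the proenkephalin gene Penk by 2.22 and the actin-binding gene Xirp2 by 2.18. The smallest p belonged to Pdk4, the kinase that inhibits pyruvate dehydrogenase, which fell by 1.35 (SE 0.07, edgeR adjusted p 3.7e-05), from 81.6 ± 5.58 to 32.0 ± 1.96 CPM. The matrix glycoprotein Tnc fell by 0.96 (SE 0.08, adjusted p 8.5e-04), from 1922 ± 181 to 986 ± 40.1 CPM. Fgd3 fell by 1.00, the Hippo pathway scaffold Amot by 1.09 and the poliovirus receptor Pvr by 0.80. Of the 28 genes that the rule takes by fold or p, 18 passed in each fit that left out 1 library. Of the others, Crisp1, Clca3b, Lad1, Ggt5, Arc, Upk1b, Vmn2r79, Penk and Xirp2 lost the call in 1 to 7 of the 8 such fits.

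**Figure D1:**
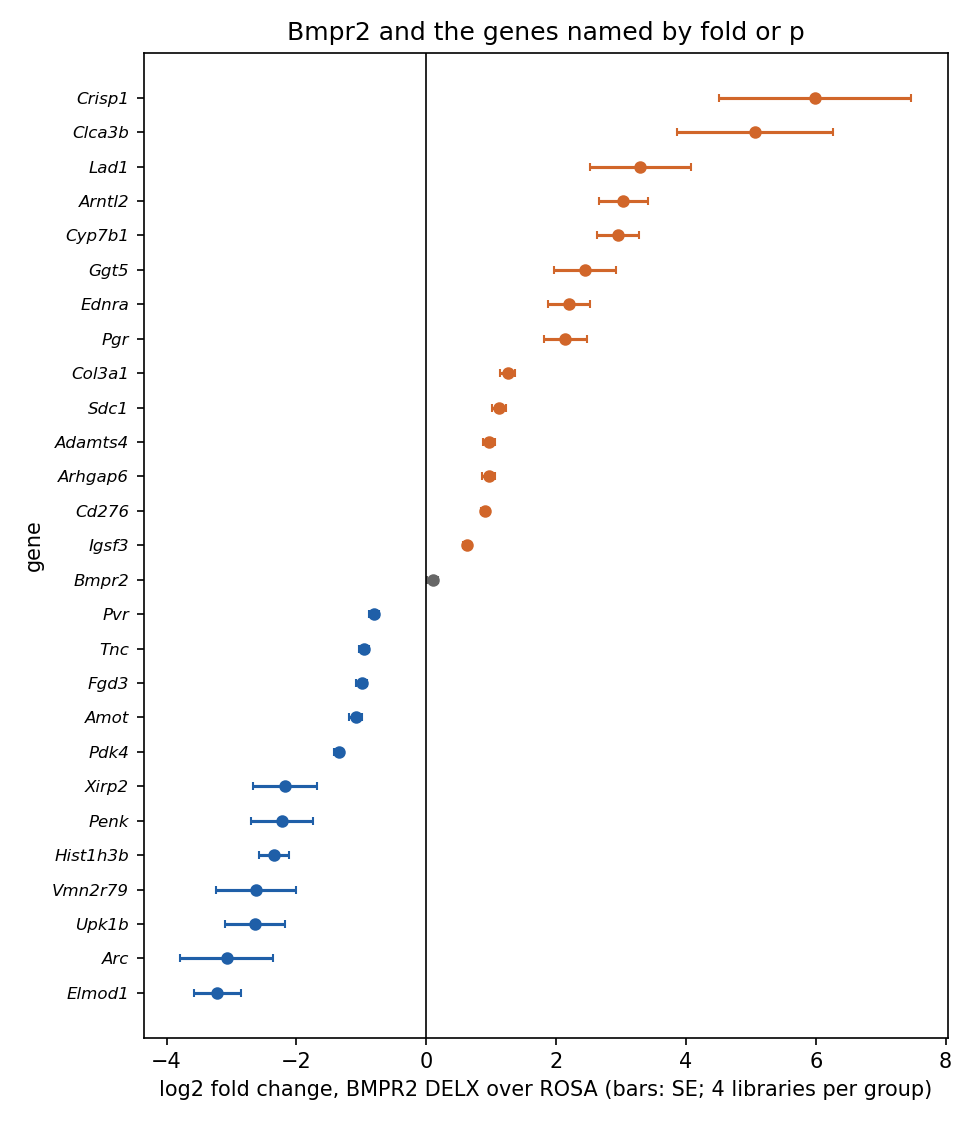
Log2 fold change of BMPR2 DELX over ROSA on the horizontal axis for Bmpr2 and the 26 genes reported by fold or p, with points for the estimate and bars for its SE (4 libraries per group). Bmpr2 lies at 0.10, and the other genes range from -3.22 for Elmod1 to 5.99 for Crisp1.

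Interferon-responsive genes were higher as a list. Of 27 tested members of this list, 17 were higher, none (0) was lower and 10 did not pass, and adjusted over the list alone 22 were higher and 1 was lower. The immunoproteasome subunit Psmb8 rose by 1.17 ± 0.15 to 8.91 ± 1.08 CPM, the ubiquitin-like Isg15 by 1.03 ± 0.15 to 8.88 ± 1.60 CPM, the oligoadenylate synthetase-like Oasl2 by 1.63 ± 0.25 to 3.62 ± 1.22 CPM, and the peptide transporter Tap1 by 0.84 ± 0.13 to 15.9 ± 1.02 CPM, and all 4 passed without each library in turn. The median log2 fold change of the list was 0.85, and the list was called up by camera (adjusted p 6.2e-12), with adjusted p = 0.64 with an estimated correlation. Every BMPR2 DELX library scored above every ROSA library, with 2.57 to 2.93 against 1.83 to 2.16 mean log2 CPM. Before scaling, the pan-leukocyte gene Ptprc had 0.256 ± 0.161 CPM in BMPR2 DELX and 0.362 ± 0.156 CPM in ROSA, and the macrophage complement gene C1qc had 0.412 ± 0.233 and 0.0910 ± 0.0457 CPM, both chosen after their values were seen. The macrophage list was not called (median 0.15, camera adjusted p 0.15, and adjusted p = 0.78 with an estimated correlation). Of its 13 tested genes, 10 had a positive log2 fold change, and Cd68, a lysosomal glycoprotein of phagocytes, was higher (0.72 ± 0.16, call lost in 2 of 8 fits without 1 library) and 12 did not pass. Adjusted over the list alone 3 macrophage genes were higher. Lyz2, the lysozyme of myeloid cells, had 11.5 ± 6.11 against 4.06 ± 1.65 CPM and Mpeg1, a perforin-like macrophage gene, had 2.42 ± 1.57 against 0.653 ± 0.347 CPM, and neither passed.

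Immediate early genes were lower as a list. Of 29 tested, 6 were lower, 23 did not pass, and adjusted over the list alone 19 were lower. Maff, a small Maf factor, fell by 0.68 (SE 0.08), the nuclear receptor Nr4a2 by 1.44 (SE 0.24), and the Krüppel-like factor Klf6 by 0.76 (SE 0.17). The list median was -0.72 (camera adjusted p 1.8e-07, and adjusted p = 0.69 with an estimated correlation). The score was uneven among the controls, at 6.77 in ROSA 1 and 6.95 in ROSA 2 but 5.65 in ROSA 3 and 5.64 in ROSA 4, against 5.35 to 5.53 in BMPR2 DELX. ROSA 1 also had the highest share of reads not assigned to a gene (unmapped, multimapping, outside annotated genes or ambiguous), 22.0%. Without ROSA 1 and ROSA 2, which were set aside after seeing these values, the list median was -0.21 with a camera adjusted p of 0.0060. Of the genes named in this paragraph, Maff and Nr4a2 passed without each library in turn, and Klf6 lost the call in 5 of 8 fits.

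Cell cycle genes rose as a list, with 6 of 27 higher, 21 not passing, and 15 higher when adjusted over the list alone. The mitotic kinase Plk1 rose by 0.63 ± 0.12, the anaphase-promoting complex activator Cdc20 by 0.52 ± 0.10 and the spindle checkpoint kinase Bub1b by 0.63 ± 0.14, with the call lost in 1, 1 and 3 of 8 fits without 1 library. The median was 0.32 (camera adjusted p 3.0e-06, and adjusted p = 0.78 with an estimated correlation). BMPR2 DELX 4, at a score of 5.61, lay within the range of ROSA, 5.58 to 5.79, and the other BMPR2 DELX libraries lay at 6.02 to 6.17. Ribosomal protein genes were shifted slightly up, with a median of 0.09 over 47 genes, 46 of them positive and 0 called by edgeR, among all genes or adjusted over the list alone. Of these genes 7 had an unadjusted p below 0.05, DESeq2 called 1 and voom 0. Camera called that list at an adjusted p of 1.3e-04, with adjusted p = 0.78 with an estimated correlation. The estimated inter-gene correlation was 0.65, so the shared sign of its members is not independent evidence. In the ribosomal score, BMPR2 DELX 3, at 8.43, lay within the range of ROSA, 8.41 to 8.45. The other BMPR2 DELX libraries lay at 8.46 to 8.61.

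**Figure D2:**
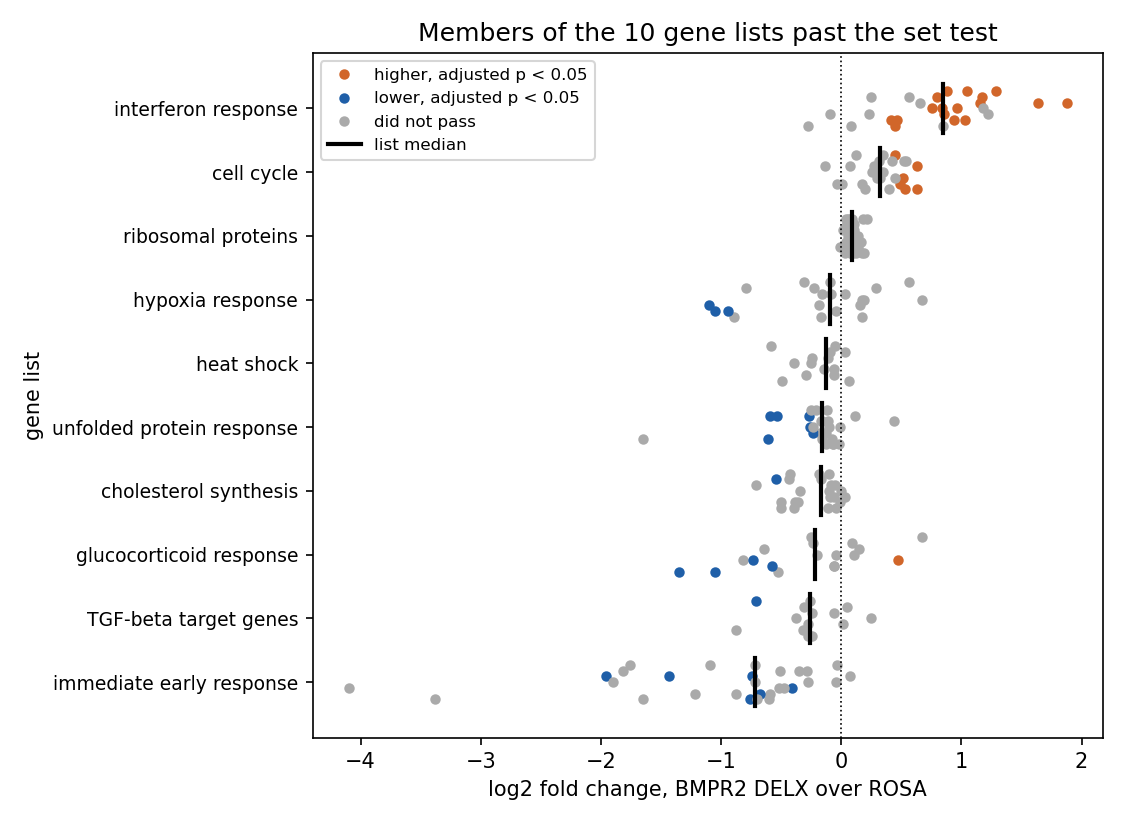
Log2 fold change of BMPR2 DELX over ROSA for each tested member of the 10 gene lists called by camera, 1 point per gene, coloured by the edgeR call, with a black line at the list median. The medians run from -0.72 for immediate early genes to 0.85 for interferon-responsive genes.

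The lists of receptors and ligands and of BMP-SMAD targets had members in both directions, and neither was called. Among 36 receptors, ligands and antagonists, 1 was higher, 3 were lower and 32 did not pass, and adjusted over the list alone 3 were higher and 6 lower. The activin receptor Acvr1b rose by 0.58 ± 0.09, the follistatin-like Fstl3 fell by 0.39, the BMP antagonist Grem1 fell by 2.01 (from 124 ± 65.4 to 30.9 ± 10.9 CPM), and the activin subunit Inhba fell by 0.36. The median of that list was -0.005 with TMM and 0.04 with upper-quartile factors (camera adjusted p 0.78, and adjusted p = 0.90 with an estimated correlation). Of 17 BMP-SMAD target genes, 3 were higher, 2 lower and 12 did not pass, with the same counts, 3 and 2, adjusted over the list alone. The helix-loop-helix inhibitor Id3 rose by 0.48 ± 0.09 and the homeobox gene Msx1 by 0.67 ± 0.16, while its paralog Msx2 fell by 1.15 and the inhibitory Smad7 by 0.45. The list was not called (median -0.11, camera adjusted p 0.99, and adjusted p = 0.99 with an estimated correlation). Acvr1b and Id3 passed without each library in turn, and the other 6 genes named here lost the call in 3 to 7 of 8 such fits.

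TGF-beta target genes were lower as a list, although 1 of 15 passed, 14 did not, and 1 was lower adjusted over the list alone. The transcriptional repressor Tgif1 fell by 0.71 (SE 0.18), and the clock-related repressor Bhlhe40 had a log2 fold change of -0.88 ± 0.31 with an edgeR adjusted p of 0.12. Both stood high in ROSA 1 and ROSA 2, with 86.4 and 101.7 CPM of Tgif1 and 185 and 250 CPM of Bhlhe40. ROSA 3 and ROSA 4 had 57.1 and 57.7 CPM of Tgif1 and 98.5 and 94.9 CPM of Bhlhe40. The list score was 9.83, 9.90, 9.69 and 9.73 in ROSA 1 to 4, against 9.43 to 9.64 in BMPR2 DELX. The list median was -0.26 (camera adjusted p 0.014, and adjusted p = 0.64 with an estimated correlation). Tgif1 lost the call in 6 of the 8 fits without 1 library.

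Matrix and fibroblast genes changed in both directions. Of 37 extracellular matrix genes, 5 were higher, 3 lower and 29 did not pass, and adjusted over the list alone 7 were higher and 4 lower. Besides Col3a1 and Tnc, the fibril-associated collagen Col14a1 rose by 1.92 ± 0.24 and the thrombospondin Thbs2 by 1.04 ± 0.17. Of 22 progenitor and fibroblast genes, 4 were higher, 4 lower and 14 did not pass, and adjusted over the list alone 5 were higher and 5 lower. Islr, a marker of stromal cells, rose by 1.75 ± 0.23, while the semaphorin Sema3c fell by 1.14 and the preadipocyte factor Dlk1 by 2.58 (from 1.66 ± 1.05 to 0.281 ± 0.147 CPM). Neither list was called, with camera adjusted p of 0.37 and 0.69, and adjusted p = 0.85 for both with an estimated correlation. Dlk1 lost the call in 3 of the 8 fits without 1 library. The endothelial list, with 24 tested genes and 0 called over all genes or adjusted over the list alone, scored lowest in BMPR2 DELX 3, 3.64, and ROSA 3, 4.11, against 4.60 to 5.38 in the other libraries. In that list edgeR gave 2 genes an unadjusted p below 0.05, DESeq2 called 1 higher and 1 lower, and voom called 0. The list median was -0.06 (camera adjusted p 0.57, and adjusted p = 0.90 with an estimated correlation).

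Of 18 tested adipocyte identity genes, 1 was higher, 2 were lower and 15 did not pass, and adjusted over the list alone 4 were higher and 3 lower. The growth hormone receptor gene Ghr fell by 0.47 (SE 0.07, edgeR adjusted p 0.0050), the lipid droplet coat gene Plin2 fell by 0.54 (SE 0.12), and the lipoprotein lipase gene Lpl rose by 0.58 ± 0.13. The list had a median of -0.08 and a mean of 0.05, and was not called (camera down, adjusted p 0.69, and adjusted p = 0.90 with an estimated correlation). Of 25 fatty acid and triglyceride synthesis genes, 4 were higher, 1 was lower and 20 did not pass, with 7 higher and 1 lower adjusted over the list alone. The desaturases Fads2 (0.21 ± 0.05) and Scd2 (0.49 ± 0.13) and the acyltransferase Gpam (0.61 ± 0.15) rose, and the list was not called (median 0.10, camera adjusted p 0.064, and adjusted p = 0.73 with an estimated correlation). Of 24 fatty acid oxidation genes, 2 were higher, 2 lower and 20 did not pass, with 2 and 2 adjusted over the list alone. Pdk4 and the carnitine acyltransferase Cpt1a fell, by 1.35 and 0.42, while Hadh (0.32 ± 0.07) and Cpt2 (0.35 ± 0.08) rose, with a list median of 0.04 (camera adjusted p 0.41, and adjusted p = 0.85 with an estimated correlation). Ghr and Pdk4 passed without each library in turn, and the other genes named here lost the call in 1 to 7 of 8 fits.

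Cholesterol synthesis genes were lower as a list, with 1 of 23 lower, 22 not passing, and 1 lower adjusted over the list alone. The sterol desaturase Sc5d fell by 0.54 (SE 0.10), and the sterol oxidase Msmo1 had a log2 fold change of -0.50 ± 0.15 with an edgeR adjusted p of 0.074. The median was -0.17 (camera adjusted p 0.016, and adjusted p = 0.78 with an estimated correlation). The list was no longer called without BMPR2 DELX 3 (adjusted p 0.052), ROSA 1 (0.14) or ROSA 2 (0.17), and its median was 0.044 without both ROSA 1 and ROSA 2.

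The unfolded protein and heat shock lists were lower in camera with the preset correlation. Of 27 unfolded protein response genes, 6 were lower, 21 did not pass, and 8 were lower adjusted over the list alone. The endoplasmic reticulum co-chaperone Dnajb9 fell by 0.61 (SE 0.12), the serine synthesis enzyme Phgdh by 0.59 (SE 0.12) and the chaperone Calr by 0.26 (SE 0.06), with the call lost in 1, 1 and 6 of 8 fits without 1 library. That list had a median of -0.16 (camera adjusted p 1.3e-04, and adjusted p = 0.64 with an estimated correlation). Of 14 heat shock genes, 0 passed in edgeR over all genes or adjusted over the list alone, 4 had an unadjusted p below 0.05, DESeq2 called 3 and voom 1 lower, and the median was -0.13 (camera adjusted p 0.023, and adjusted p = 0.69 with an estimated correlation). The heat shock list lost the call without BMPR2 DELX 3 (0.052), ROSA 2 (0.073) or ROSA 3 (0.055).

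Of 21 hypoxia-responsive genes, 3 were lower and 18 did not pass, with 4 lower adjusted over the list alone. The lipase inhibitor Angptl4 fell by 1.05 (SE 0.10), the prolyl hydroxylase Egln3 by 0.95 (SE 0.09) and Ankrd37 by 1.10 (SE 0.24), and the list median was -0.09 (camera adjusted p 0.025, and adjusted p = 0.64 with an estimated correlation). Of 18 glucocorticoid-responsive genes, 1 was higher, 4 were lower and 13 did not pass, with 1 and 4 adjusted over the list alone. Pdk4, Angptl4 and the kinase gene Sgk1, which fell by 0.74 (SE 0.16), were among the lower members, and the factor Cebpd rose by 0.47 ± 0.12. Without 1 library, Ankrd37, Sgk1 and Cebpd lost the call in 3, 4 and 7 of 8 fits, and Pdk4, Angptl4 and Egln3 in 0. The median was -0.22 (camera adjusted p 0.030, and adjusted p = 0.64 with an estimated correlation). The hypoxia list lost the call without BMPR2 DELX 2 (0.058) or ROSA 4 (0.084), and the glucocorticoid list without ROSA 1 (0.051) or ROSA 2 (0.098).

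Of 19 tested inflammatory cytokine and chemokine genes, 1 was higher, 4 were lower and 14 did not pass, with 1 and 5 adjusted over the list alone. The prostaglandin synthase Ptgs2 fell by 1.77 (SE 0.23, edgeR adjusted p 0.0050), from 1624 ± 537 to 476 ± 61.9 CPM, and passed without each library in turn. The chemokines Cxcl5 and Ccl7 fell by 1.37 and 0.40, and the receptor antagonist gene Il1rn rose by 1.32 ± 0.34, and these 3 lost the call in 6 or 7 of 8 fits without 1 library. The list was not called (median -0.40, camera adjusted p 0.15, and adjusted p = 0.78 with an estimated correlation). Of 32 insulin signalling genes, 1 was higher, 4 were lower and 27 did not pass, with 1 and 5 adjusted over the list alone. The phosphoinositide kinase subunit Pik3cb fell by 0.40 (SE 0.08) and the receptor substrate Irs2 by 0.49 (SE 0.10), and each lost the call in 1 of 8 fits without 1 library. That list had a median of -0.03 with TMM and 0.01 with upper-quartile factors (camera adjusted p 0.41, and adjusted p = 0.78 with an estimated correlation).

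In total, 10 of the 37 lists with enough members were called by camera with the preset correlation, 3 up and 7 down. None (0) was called with an estimated correlation, where the smallest adjusted p was 0.64, and fry called 5 in a direction, 4 of them among these 10 and the other, nerve and glia, not called by camera (fry adjusted p 0.031, down).

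**Figure D3:**
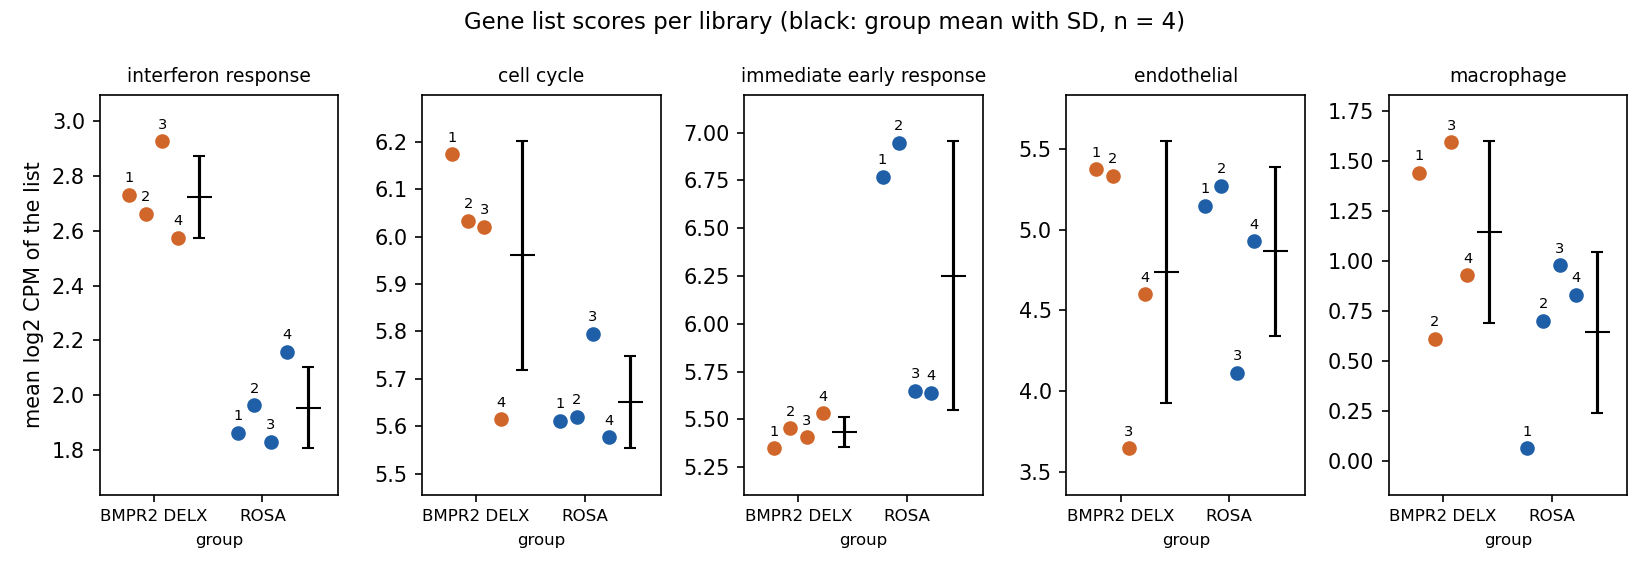
Mean log2 CPM of 5 gene lists per library, 1 point per library with its replicate number, with the group mean and SD in black (n = 4). The interferon scores of BMPR2 DELX, 2.57 to 2.93, lie above those of ROSA, 1.83 to 2.16, and the immediate early scores of ROSA 1 and ROSA 2, 6.77 and 6.95, stand apart.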

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

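The test over splits of the libraries, and the tests of explanations for the interferon and immediate early patterns and for the Phgdh copies, were chosen only after the results were seen. The search for single libraries far from the rest of their group followed a rule fixed beforehand. It compared the gap of the extreme library to its nearest neighbour with the range of its group, against Dixon's critical value. Of 282 groups of values examined, 21 (7.45%) passed, where chance flags about 1 in 20 groups.

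Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 1355 called genes. The highest of the other splits gave 2. A share of 1 in 35 is the smallest that this test can give. Each of the other splits mixes the groups, so few calls would follow there whenever the groups differ for any reason. The test therefore cannot exclude chance assignment of the libraries, nor tell a genotype effect from another difference between the groups.

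Interferon-responsive genes were higher in BMPR2 DELX, with a list median of 0.85. More macrophages in the BMPR2 DELX samples is 1 candidate explanation, but with the macrophage score as a covariate the median was still 0.77 and the list was still called by camera with the preset correlation (adjusted p 8.6e-11, 1.0e-17 to 6.9e-10 over all fits with that correlation). A different share of endothelial cells is another, and with the endothelial score as a covariate the median was 0.85 (adjusted p 1.5e-11). The endothelial score differed little between the groups (4.74 ± 0.81 in BMPR2 DELX and 4.87 ± 0.52 in ROSA), so that covariate could hardly move the median. The overlap of the groups in this score itself argues against the endothelial share as the whole source. The macrophage score covers 13 tested genes and leaves out those with too few counts, such as C1qc. It is an incomplete measure of macrophages, so their part in the pattern stays open. With an estimated correlation the list was not called (adjusted p = 0.64 with all libraries). A response of the cells to the BMPR2 DELX genotype may underlie the pattern as a hypothesis, and it was not tested separately, nor was an exposure shared by the samples of 1 group.

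Immediate early genes were lower in BMPR2 DELX, with a list median of -0.72. RNA quality is a candidate explanation, since ROSA 1 had the highest share of reads not assigned to a gene, 22.0%. With that share as a covariate the median was -0.64 and the list was still called by camera with the preset correlation (adjusted p 1.1e-06). Over all fits with that correlation the camera adjusted p ran from 7.1e-11 to 0.0060. The list was not called with an estimated correlation (adjusted p = 0.69) or by fry (0.13), both with all libraries and no covariate. ROSA 2, with the highest immediate early score, 6.95, had a share of 16.1%, inside the BMPR2 DELX range of 14.7% to 17.3%. The covariate therefore could not take up the excess of ROSA 2. It also does not measure RNA integrity, so RNA quality stays open. A response in ROSA 1 and ROSA 2 alone, such as handling of those samples, is another candidate explanation. With both left out, the median of the list without Fosb and Egr3, which helped to single out these libraries, was -0.21 against -0.70 with all libraries. Leaving out these genes does not undo the selection, since the score of the whole list also set ROSA 1 and ROSA 2 apart. The whole list was still called by camera with the preset correlation (adjusted p 0.0060). The excess in ROSA 1 and ROSA 2 and a lower level in BMPR2 DELX cannot be told apart for this list, because the libraries were picked for their high values and few remain, and a biological difference between the genotypes stays open, untested.

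Of 4 tested copies of Phgdh, chosen after their values were seen, 3 were higher in BMPR2 DELX while Phgdh fell by 0.59. A constant share of Phgdh reads assigned to its copies would lower them too, but the median log2 fold change of all 4 was 3.88, which argues against it for the copies that rose. The copy most similar to Phgdh, Gm7901, had a log2 fold change of 0.39 and did not pass. A strain difference around Phgdh that sends some of its reads to copies could also act: 14.5% of the 124 genes tested within 5 Mb of Phgdh were called, against 9.11% of all placed genes, and 7.17% of the windows around other genes reached that share. This does not decide the matter, and a strain difference cannot be told apart from transcription of the copies themselves, since the files hold no reads. A biological effect of the genotype stays open, untested.

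The remaining values far from the rest of their group are in TMM-scaled CPM unless said otherwise, and no explanation was tested for them. Crisp1 was at 10.9 in BMPR2 DELX 3 (others 0.469 to 1.47) and at 0.186 in ROSA 1 (others 0 to 0.0243). ROSA 4 was high for Ggt5 at 2.60 (others 0.532 to 0.655), Pgr at 10.3 (others 3.76 to 4.85), Acvr1b at 19.0 (others 15.8 to 16.4) and Chac1 at 16.3 (others 12.7 to 13.04). BMPR2 DELX 2 had 84.8 for Cd276 (others 79.2 to 79.7). BMPR2 DELX 4 had 56.2 for Plk1 (others 75.1 to 76.2). BMPR2 DELX 3 had 10.5 for Psmb8 (others 8.35 to 8.41), 11.3 for Isg15 (others 7.98 to 8.13) and 11.3 for Esr1 (others 8.90 to 9.16). ROSA 3 had 224.6 for Ghr (others 200.1 to 202.6), 55.4 for Plk1 (others 42.03 to 43.1) and 21.5 for Aurkb (others 17.4 to 17.9).

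The 10 most abundant genes took 9.13% of the counts of BMPR2 DELX 3, against 6.89% to 7.26% in the other BMPR2 DELX libraries. ROSA 1 had a higher share, 11.7%, which did not pass the rule within its group. The gene Gm42418 had 30517 CPM before scaling in BMPR2 DELX 3 and 6206 to 18546 CPM in the other BMPR2 DELX libraries. It had 58241 CPM in ROSA 1 and 4113 to 21474 CPM in the other ROSA libraries. Among list scores in mean log2 CPM, ROSA 3 was at 4.38 for BMP-SMAD target genes (others 4.67 to 4.69), 5.37 for progenitor and fibroblast genes (others 5.68 to 5.71), 5.89 for oxidative stress genes (others 5.68 to 5.71) and 3.85 for adrenergic and lipolytic genes (others 4.04 to 4.07). ROSA 1 was at 4.24 for adipocyte identity genes (others 4.33 to 4.34), and BMPR2 DELX 1 was at 5.25 for hypoxia genes (others 5.03 to 5.04).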

How the results depend on the processing

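The fits with a covariate, those without ROSA 1 together with BMPR2 DELX 3 or ROSA 2, and the list tests with upper-quartile factors or no filter were chosen after the data were seen. Higher and lower counts stayed within 1.5 times 589 and 766 with other scaling factors, other filters, voom (755 and 882), the unstranded column (638 and 685) and the endothelial covariate (751 and 924). DESeq2 called 1082 and 1186 genes; the cause was not tested. With the replicate number as a block the counts were 563 and 682, of which 448 and 558 were shared. The numbers were taken to pair the samples only if all 4 correlations of same-numbered deviations exceeded 0.1. They were 0.005, 0.21, 0.24 and 0.09, so the rule was not met. Of these, 0.21 and 0.24 were above all unmatched pairs, and 0.005 and 0.09 were below some. A preparation shared by some same-numbered samples is not ruled out. Leaving out 1 library gave 213 to 545 higher and 264 to 721 lower genes. These moved by over 1.5 times without BMPR2 DELX 1 (483 lower), BMPR2 DELX 2 (290 and 369), BMPR2 DELX 3 (367 and 503), ROSA 1 (300 and 331) and ROSA 2 (213 and 264). Counts were 163 and 244 without ROSA 1 and BMPR2 DELX 3, and 64 and 108 without ROSA 1 and ROSA 2, where fewer libraries remain. As a covariate, the macrophage score gave 164 and 248. The share of reads not assigned to a gene gave 215 and 317, and the cause was not tested for either covariate. No call changed sign in these fits except 1 with the unstranded column. Bmpr2 did not pass in any fit, with a log2 fold change of 0.05 to 0.16 without 1 library. The number of lists called, 10, was 0 with an estimated correlation and 5 with fry, tests built on other assumptions, and 8 to 11 without 1 library. Without ROSA 1 and ROSA 2, Egr3 had a log2 fold change of 0.13 and the cholesterol synthesis median was 0.044; the cause was not tested beyond the removal of these libraries. In the simulation with 4 libraries per group, 28.4% of the 67 genes changed by 0.5 were called. Few of its 14711 genes were changed at any size, while 1355 were called in these data. With fewer changed genes the Benjamini-Hochberg cut-off is stricter, so the share of small changes missed in these data is not known.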

Other observations

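The counts for the Phgdh copies, the histone genes and the chromosome 3 genes, and the genes Pax8, Cdh16, Krt8, Krt7, Krt18, Cldn4, Fosb, Sprr1a and Tap2, were chosen only after values were seen. The gene lists were fixed beforehand.

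For the histone genes of the replication-dependent clusters there was no fixed list and no set test was made. Of 30 such genes tested, 29 had a negative log2 fold change, and 7 were lower, 0 higher and 23 not called in edgeR, with a median of -0.61 (-0.57 with upper-quartile factors). Polyadenylated RNA was sequenced, so these counts cover only polyadenylated forms of the histone transcripts. A fall in them need not be a fall in all histone mRNA. Hist1h3b fell by 2.35 and Hist1h2ab, an H2A gene, by 1.88, from 2.69 to 0.718 CPM, at low levels throughout. Hist1h2bc, an abundant H2B gene, fell by 0.61, from 44.6 to 29.1 CPM. In a part of the epidermal differentiation cluster on chromosome 3, from 90654017 to 93014205, 14 genes were tested, with no set test. Of these 7 were lower, 0 higher and 7 did not pass. The ends were set at S100a7a and Crct1, both called lower, which raises this share. Among all 14887 genes tested, 766 were lower. The fixed keratinocyte and hair follicle list had 0 of 6 tested genes called, and 1 lower adjusted over the list alone. It was not called (camera adjusted p 0.15, and adjusted p = 0.64 with an estimated correlation). The late cornified envelope genes Lce1f and Lce1g fell by 2.74 and 1.72, the cysteine-rich Crct1 by 1.80, from 24.5 to 7.01 CPM, and the S100 gene S100a7a by 1.92. The small proline-rich gene Sprr1a, in the same run, had a log2 fold change of 2.15 ± 0.73 (1.31 without BMPR2 DELX 3), with 10.9 ± 10.7 against 2.43 ± 0.485 CPM, and did not pass.

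Tap2, the partner of Tap1 in peptide transport and not a member of the interferon list, rose by 0.39 ± 0.10 and lost the call in 6 of 8 fits without 1 library. Of 17 circadian clock genes, 2 were lower and 15 did not pass, with 4 lower adjusted over the list alone, and the deubiquitinase Usp2 and the period gene Per1 fell by 0.38 and 0.57 (camera adjusted p 0.15, and adjusted p = 0.69 with an estimated correlation). Of 27 oxidative stress genes, 2 were higher and 25 did not pass, with 1 higher adjusted over the list alone, and the glutathione transferases Gsta3 and Gstm1 rose by 1.46 and 0.54 (camera adjusted p 0.17, and adjusted p = 0.82 with an estimated correlation). Of 17 glycolysis genes, 1 was lower and 16 did not pass, with 1 lower adjusted over the list alone, and the pyruvate kinase Pkm fell by 0.27 (camera adjusted p 0.15, and adjusted p = 0.78 with an estimated correlation). Of 18 adrenergic and lipolytic genes, 2 were higher and 2 lower, with 3 and 4 adjusted over the list alone. Their median was -0.08, their mean 0.001 and the test pointed down (camera adjusted p 0.78, and adjusted p = 0.90 with an estimated correlation), and the adenylyl cyclases Adcy5 and Adcy3 rose by 1.11 and 0.48. Of 45 nuclear genes of oxidative phosphorylation, 0 passed in edgeR over all genes or adjusted over the list alone, 4 had an unadjusted p below 0.05, DESeq2 called 1 and voom 0. Without 1 library, Usp2 lost the call in all 8 fits, Gstm1 and Pkm in 7, Per1, Adcy5 and Adcy3 in 6, and Gsta3 in 1.

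Of the lists for other cell types, the 5 with enough members named here were not called by camera (adjusted p 0.15 to 0.78). Of 13 smooth muscle and pericyte genes, the proteoglycan Cspg4 fell by 1.04 and Notch3 rose by 0.96, with 1 and 1 adjusted over the list alone. Of 9 skeletal muscle genes, the actin Acta1 fell by 1.35, from 447 ± 106 to 176 ± 53.4 CPM, and 8 did not pass, with 0 higher and 1 lower adjusted over the list alone. Of 10 nerve and glia genes, 3 were lower and 0 higher, with 3 and 0 adjusted over the list alone, and Uchl1 and Tubb3 fell by 0.69 and 0.68, and fry called that list down (adjusted p 0.031) where camera did not (0.15). The endocytic receptor Lrp2, 1 of 2 liver and kidney genes tested, fell by 1.81, from 114 ± 16.7 to 32.3 ± 15.1 CPM. Of 11 mammary and glandular epithelium genes, Pgr and the estrogen receptor Esr1 were higher and 9 did not pass, with 3 higher and 1 lower adjusted over the list alone. Of 11 mesothelial genes, Upk1b was lower and 10 did not pass, with 1 higher and 2 lower adjusted over the list alone, and the list had a median of 0.24 and a mean of 0.21 while the test pointed down (camera adjusted p 0.78, and adjusted p = 0.90 with an estimated correlation). Pax8, a factor of kidney and Müllerian epithelium, was higher by 3.38 ± 0.87 (2.49 without BMPR2 DELX 3) and lost the call in 7 of 8 fits without 1 library. It had 0.938, 2.02, 4.49 and 0.298 CPM before scaling in BMPR2 DELX 1 to 4 and 0.0579 to 0.304 CPM in ROSA. Cdh16, which did not pass, had 0.799, 1.87, 4.58 and 0.0687 CPM in BMPR2 DELX 1 to 4 and 0 to 0.456 CPM in ROSA. The keratins Krt8 and Krt7 were also highest in BMPR2 DELX 3, at 11.2 and 13.1 CPM, while Krt18 and Cldn4 were highest in other libraries. Y-linked Ddx3y had 83.6 ± 16.8 CPM in BMPR2 DELX and 82.3 ± 2.40 CPM in ROSA, and Xist had at most 0.0694 CPM before scaling in any library. Without 1 library, Cspg4, Notch3 and Tubb3 lost the call in 6 of 8 fits, Esr1 in 4, Lrp2 in 2, Uchl1 and Upk1b in 1, and Acta1 and Pgr in 0.

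Of 25 annotated genes that resemble Phgdh, 4 had enough counts to be tested and 3 were higher. Some of the others overlap each other in position, and some, such as Gm5207, are absent from the deposited counts. The log2 fold changes of the 3 higher copies were 3.76 for Gm9347 (chromosome 7, 136810909 to 136812515), 4.01 for Gm13337 (chromosome 2, 22067826 to 22069419) and 4.34 for Phgdh-ps1 (chromosome 7, 83710966 to 83711719), the last at 5.20 without ROSA 2. Raw counts per library were 144 to 182 in BMPR2 DELX and 9 to 18 in ROSA for Gm9347. They were 26 to 49 and 1 to 3 for Gm13337, and 13 to 22 and 0 to 2 for Phgdh-ps1. With so few ROSA counts, the size of the folds of Gm13337 and Phgdh-ps1 is uncertain. The most similar tested copy, Gm7901, with 98.7% identity, had a log2 fold change of 0.39 and an edgeR adjusted p of 0.25. Fosb, the immediate early gene with the widest spread, had 73.2 CPM in ROSA 1 and 153 CPM in ROSA 2 before scaling, against 3.19 to 7.65 CPM in the other libraries.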
